A study of Arabidopsis thaliana with 27 samples.

How the data were processed

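Total RNA from etiolated hypocotyls was made into TruSeq stranded libraries and sequenced, per the labels' protocols. The authors deposited a table of raw counts per gene for 32832 loci, of which 26893 had a count in at least 1 of 27 libraries. Per the submitters' notes, reads were checked with FastQC, trimmed with Trimmomatic and aligned with HISAT2, and DESeq2 was used, with no versions. The genome build, the read counter and the handling of reads shared by genes are not given in the sources used here. The authors also deposited a table of normalised counts, here called signal, which a note in the file says was made with DESeq. The deposited signal equalled the count divided by 1 factor per library (largest difference 7.6e-10 counts), and it served only to recover those factors.

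Libraries were grouped by genotype and dose from the labels. Symbols came from the reference annotation or the authors' gene names, and 32547 loci were matched.

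Genes were tested from the raw counts with the edgeR quasi-likelihood test (R 4.3.3, edgeR 4.0.16, limma 3.58.1), with TMM factors and the default low-count filter, which kept 19794 genes. All libraries entered 1 fit of 9 groups with 18 residual degrees of freedom and a robust prior. Each comparison was a contrast of that fit, two-sided, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. A difference of responses was the change in the mutant minus the change in WT. CPM values used TMM-scaled totals, and the prior count of log2 values was 2. A passing gene is called higher or lower, or said to rise or fall with the dose.

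The 21 gene lists (380 loci, 350 tested), the comparisons, their tests and most alternatives were fixed before the data were examined. The lists covered the UVR8 pathway, flavonoid and phenylpropanoid synthesis, DNA damage response, UV lesion repair, DNA replication, mitosis, auxin, cell wall expansion, gibberellin, brassinosteroid, light harvesting and photosystems, dark growth and shade, defence, oxidative stress, heat shock, ethylene, jasmonate and abscisic acid. Seed storage, root, and shoot apex and stomata lists stood for other tissues. Each list with at least 5 measured members was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Camera asks whether a list moves relative to all other genes.

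Named genes were the targeted ones, those with the largest increases and decreases that passed the test, had no overlap between the replicates compared and a mean log2 CPM of at least 1, and in each list up to 4 passing members with the smallest p, given in order of p. The condition of no overlap was not applied to differences of responses. Text drops genes only from the end of each list's ranking.

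Alternatives were DESeq2 (version 1.42.0), DESeq2 size factors, no low-count filter, a fit on the compared groups alone and a replicate block. Each library was also left out in turn. Added after the results were seen were the authors' factors, a block within each genotype and leaving out libraries that stand apart. So were a GC and length correction and thinning to the lowest depth. Libraries of the same replicate number deviated together in all dose comparisons of uvr8-6 (lowest correlation 0.255). Of the others only WT dark and low dose did (0.442, 0.109 and 0.314), but different numbers reached 0.416. In separate runs, xpf-3 low and uvr8-6 high dose libraries paired too (lowest 0.182). What a number marks is not labelled, so this pairing comes from the data.

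The tests were tested on simulated data with 200 changed genes of mean CPM at least 2. For WT at the low dose edgeR recovered 78% of 2-fold and 98% of 4-fold changes with 9 false calls, and for the xpf-3 difference at the high dose 49% and 91% with 6. The real comparisons passed 5064 and 1849 genes, so these rates may not hold there. No coordinates or splice forms were analysed here.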

Results

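Etiolated Arabidopsis hypocotyls of 3 genotypes were profiled by RNA sequencing after UV-B or no exposure. The genotypes were wild type Columbia-0 (WT), xpf-3, a mutant of the repair endonuclease gene UVH1, and uvr8-6, a mutant of the UV-B photoreceptor gene UVR8. Seeds lay on 0.5× MS medium with 100 µM gibberellin A4 and grew for 2.5 days in the dark. They then stayed dark or received 3000 or 30000 µmol m-2 of UV-B over about 5 or 45 min, and went back to the dark. The extraction protocol puts the harvest 6 h after exposure, while the series title says 2 days. Each of the 9 groups held 3 libraries, 27 in all. Total counts per library ran from 6163441 to 11984665 in WT, from 4508097 to 11045334 in xpf-3, and from 12488317 to 15342281 in uvr8-6. The authors' notes place the WT and xpf-3 libraries in an earlier sequencing run and the uvr8-6 libraries in a later one. Run and uvr8-6 genotype hold the same libraries and cannot be told apart in any comparison of uvr8-6 with WT.

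Values after ± are the SD over the 3 libraries of a group for levels (CPM, library-scaled counts, n = 3), and the SE of the fit for log2 fold changes, each from 3 libraries per group. A p measures the spread between these libraries, which the labels do not describe as separately grown cultures. Folds against a group with 0 counts are lower bounds set by a floor of 3 counts over the group. Bounds and count intervals (95%) cover counting error only.

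The targeted genes set the genotypes apart. UVR8 (AT5G63860) stood at 3.504 ± 0.945 CPM in uvr8-6 dark (SD, n = 3) against 70.6 ± 0.994 CPM in WT dark, 4.98% of WT, and at 3.46 ± 0.257 and 3.98 ± 1.03 CPM after the low and the high dose. Transcript counts of UVH1 (AT5G41150) were higher in xpf-3 dark, 46.5 ± 6.25 CPM, than in WT dark, 19.2 ± 0.201 CPM (log2 fold change 1.27 ± 0.10, adjusted p = 1.9e-07). Counts over a whole gene do not show on which side of an insertion the reads lie. UVH1 fell after UV-B in xpf-3, with log2 fold changes of -0.60 ± 0.10 at the low and -0.45 ± 0.10 at the high dose, and in WT at the high dose, -0.30 ± 0.11. With only the 6 dark libraries of WT and xpf-3 fitted, the UVH1 difference was 1.19 and did not pass (adjusted p = 0.0863).

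**Figure D1:**
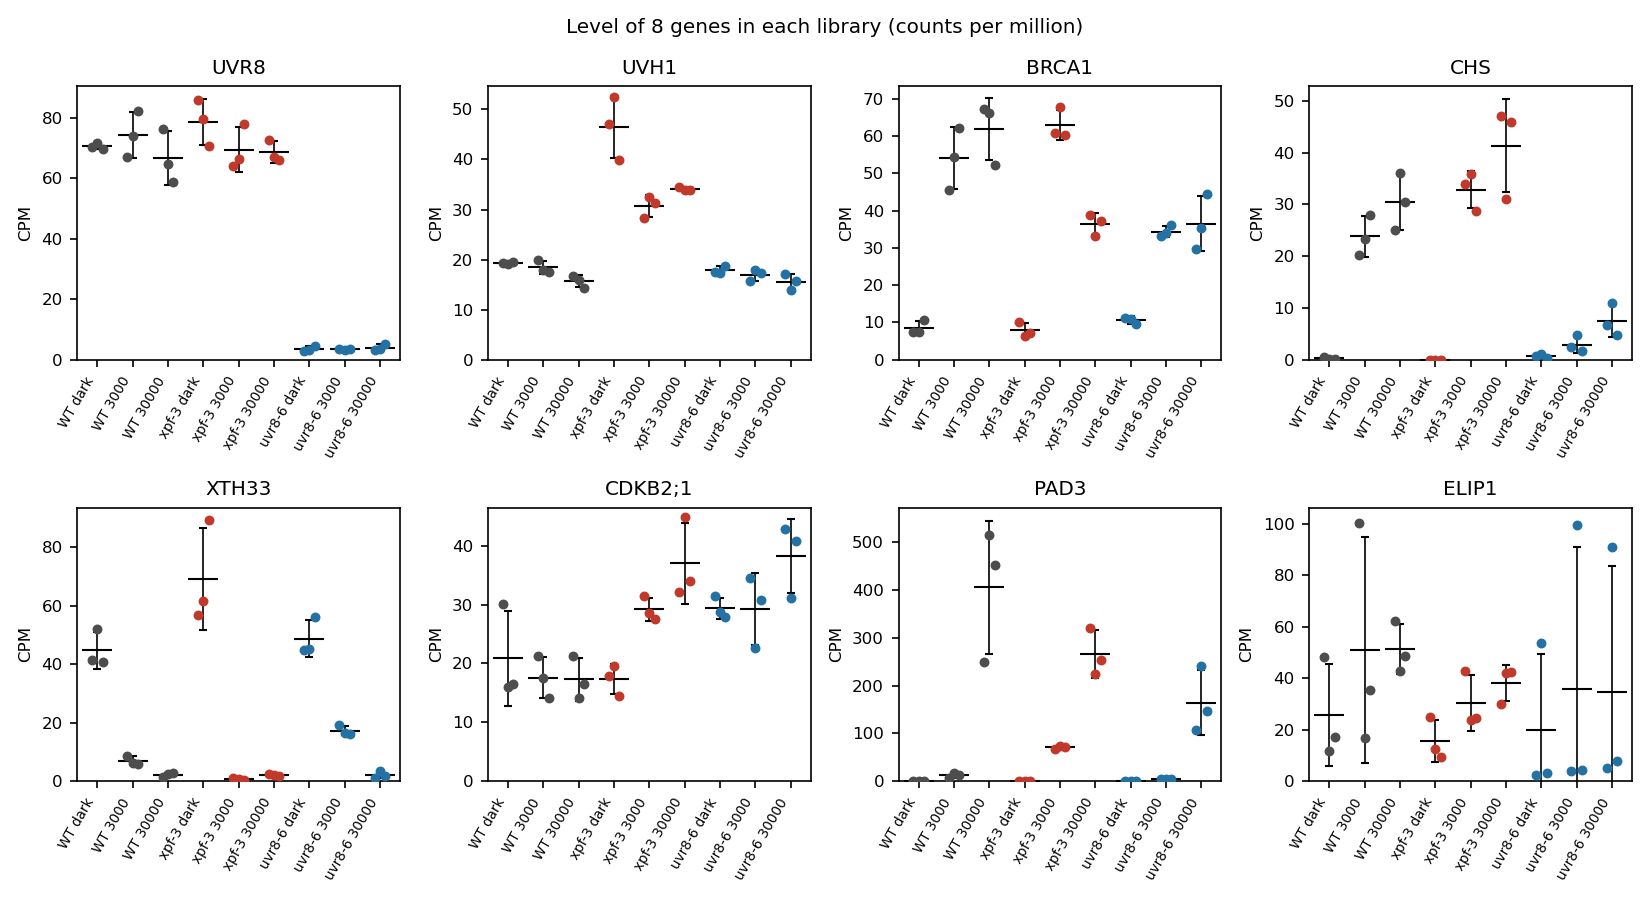
Levels (CPM) of 8 genes in each library, by genotype and dose (points, libraries; bars, mean ± SD of 3). UVR8 averaged 3.504 ± 0.945 CPM in uvr8-6 dark, and ELIP1 stood apart in replicate 2 of uvr8-6 at each dose.

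The low dose in WT was compared with the dark to find which transcripts 3000 µmol m-2 of UV-B changed. UGT74E1 (AT1G05675), a glycosyltransferase gene, went from 0 counts to 30.1 ± 13.0 CPM, at least 331-fold higher. The MATE transporter gene DTX3 (AT2G04050) rose from 0.183 ± 0.133 to 214 ± 64.6 CPM (log2 fold change 10.04 ± 0.47). Its close relative DTX4 (AT2G04070) was 1288 times higher (counting interval 231 to 50907), and NDB4 (AT2G20800), an alternative mitochondrial NADH dehydrogenase, 513 times higher (counting interval 142 to 4239.8). The split of shared reads between DTX3 and DTX4, and UGT74E1 and UGT74E2, is uncertain. The largest decreases were in PME61 (AT3G59010, -5.20 ± 0.74), a pectin methylesterase, UMAMIT17 (AT4G08300, -4.74 ± 0.66), of an amino acid transporter family, the cytochrome P450 CYP71A19 (AT4G13290, -4.60 ± 0.68) and the Nudix hydrolase NUDT8 (AT5G47240, -4.08 ± 0.66).

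After the low dose in WT, among DNA damage response genes 21 of 28 measured members rose, 0 fell and 7 did not pass (22 and 0 adjusted over the list alone). Their median log2 fold change was 1.25 (camera adjusted p = 1.3e-15, adjusted p = 0.0133 with an estimated correlation). The members with the smallest p were BRCA1 (AT4G21070, 2.66 ± 0.17), a homologous recombination factor, XRI1 (AT5G48720, 2.21 ± 0.15), TRFL10 (AT5G03780, 2.40 ± 0.18) and PARP2 (AT4G02390, 3.08 ± 0.25), a poly(ADP-ribose) polymerase. Of 21 oxidative stress genes, 14 rose and 1 fell (15 and 2 adjusted over the list alone), median log2 fold change 2.82, or 2.29 with genes at 0 set to their bound (camera adjusted p = 2.3e-12, adjusted p = 0.208 with an estimated correlation). They were led by NAC013 (AT1G32870, 3.64 ± 0.22), a transcription factor of mitochondrial retrograde signalling, AOX1A (AT3G22370, 2.82 ± 0.20), an alternative oxidase, and the glutathione transferases GSTU25 (AT1G17180, 5.10 ± 0.35) and GSTU24 (AT1G17170, 3.60 ± 0.28), whose shared reads leave each value uncertain.

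Of 23 UVR8 pathway genes, 5 rose and 0 fell (4 and 0 adjusted over the list alone), median log2 fold change 0.67 (camera adjusted p = 0.0349, adjusted p = 0.622 with an estimated correlation). Chalcone synthase CHS (AT5G13930, 6.32 ± 0.51), HYH (AT3G17609, 2.75 ± 0.66), and the sinapate glucosyltransferase UGT84A1 (AT4G15480, 2.45 ± 0.61) were among the 5. Of 13 flavonoid and phenylpropanoid genes, 4 rose and 1 fell (the same adjusted over the list alone), median log2 fold change 0.39 (camera adjusted p = 0.0349, adjusted p = 0.494 with an estimated correlation). They included the flavonol synthase FLS1 (AT5G08640, 3.62 ± 0.52) and the chalcone isomerase TT5 (AT3G55120, 1.55 ± 0.23). Of 25 light harvesting and photosystem genes, 14 rose and 0 fell (17 and 0 adjusted over the list alone), median log2 fold change 0.81 (camera adjusted p = 2.2e-05, adjusted p = 0.494 with an estimated correlation). Examples were the photosystem I subunit PSAF (AT1G31330, 0.93 ± 0.20) and the Mg-chelatase subunit GUN5 (AT5G13630, 0.77 ± 0.17). ELIP1 (AT3G22840), a light-induced chloroplast protein gene chosen after its values were seen, had 48.2 CPM in replicate 1 against 11.6 and 17.1 in the dark, and 100.3 against 16.9 and 35.4 after UV-B. Without WT UV-B 3000 replicate 1, the UVR8 pathway, flavonoid and auxin response lists no longer passed (adjusted p = 0.141, 0.158 and 0.119), nor without WT dark replicate 2 (0.134, 0.0629 and 0.0647). Without WT dark replicate 3, UVR8 pathway and flavonoid genes did not (0.0632 and 0.0579).

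In the cell wall expansion list at the low dose in WT, 0 of 24 measured members rose, 12 fell and 12 did not pass (0 and 14 adjusted over the list alone), and the median log2 fold change was -0.36 (camera adjusted p = 1.5e-04, adjusted p = 0.494 with an estimated correlation). The xyloglucan-modifying enzymes XTH33 (AT1G10550, -2.71 ± 0.23) and XTH19 (AT4G30290, -1.48 ± 0.16) fell. Of 23 auxin response genes, 0 rose and 8 fell (0 and 9 adjusted over the list alone), median log2 fold change -0.58 (camera adjusted p = 0.0162, adjusted p = 0.622 with an estimated correlation). Among them were the repressors SHY2 (AT1G04240, -1.05 ± 0.21) and IAA6 (AT1G52830, -1.71 ± 0.35). Of 13 brassinosteroid genes, 0 rose and 6 fell (the same adjusted over the list alone), median log2 fold change -0.29 (camera adjusted p = 0.0131, adjusted p = 0.494 with an estimated correlation). They included the transcription factor BES1 (AT1G19350, -0.72 ± 0.16) and the biosynthesis gene ROT3 (AT4G36380, -1.003 ± 0.22). Of 19 DNA replication genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), median log2 fold change 0.28 (camera adjusted p = 0.00266, adjusted p = 0.494 with an estimated correlation). An example was RNR1 (AT2G21790, 0.95 ± 0.15), the large subunit of ribonucleotide reductase. Of 17 defence genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone), median log2 fold change 0.79, or 0.47 with genes at 0 set to their bound (camera adjusted p = 0.0167, adjusted p = 0.494 with an estimated correlation). Among them was PAD3 (AT3G26830, 4.74 ± 0.57), of camalexin synthesis.

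In all, 5064 of 19794 tested genes passed, 2559 higher and 2505 lower, and 1856 changed at least 2-fold. DESeq2 size factors turned that majority, to 2402 and 2733. A fit on these 6 libraries alone gave 3023.

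The high dose in WT was compared with the dark. UGT74E1 went from 0 counts to 139 ± 27.9 CPM, at least 1435-fold higher. From 0 counts, FOX1 (AT1G26380), an oxidase gene, rose at least 1216-fold, CBP60G (AT5G26920), a transcription factor of salicylic acid synthesis, at least 539-fold, and HIPP14 (AT5G52760), a heavy metal-associated protein gene, at least 329.8-fold. The largest decreases were in DIR23 (AT2G21100), a dirigent protein gene, 216 times lower (counting interval 59.4 to 1784), UMAMIT17, 165 times lower (counting interval 45.4 to 1366), GDU5 (AT5G24920), 143 times lower (counting interval 25.5 to 5696), and EDA4 (AT2G48140), at least 15.701-fold lower. Defence genes included 17 of 17 that rose and 0 that fell (the same adjusted over the list alone), median log2 fold change 4.49, or 3.37 with genes at 0 set to their bound (camera adjusted p = 3.9e-07, adjusted p = 0.135 with an estimated correlation). PAD3 went from 0.453 ± 0.0863 to 406 ± 139 CPM (9.78 ± 0.51), beside the transcription factors WRKY33 (AT2G38470, 4.63 ± 0.33) and WRKY40 (AT1G80840, 3.37 ± 0.27).

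Other lists were tested at the high dose in WT. Oxidative stress genes included 18 of 21 that rose and 1 that fell (the same adjusted over the list alone), median log2 fold change 4.32 (camera adjusted p = 1.5e-08, adjusted p = 0.240 with an estimated correlation). Leading members were CYP81D8 (AT4G37370, 6.57 ± 0.31), NAC013 (4.40 ± 0.23) and AOX1A (3.62 ± 0.21). Of 28 DNA damage response genes, 22 rose and 1 fell (the same adjusted over the list alone), median log2 fold change 1.67 (camera adjusted p = 1.5e-07, adjusted p = 0.135 with an estimated correlation). The first by p were BRCA1 (2.85 ± 0.18), XRI1 (2.36 ± 0.15), TRFL10 (2.52 ± 0.19) and NAC044 (AT3G01600, 4.74 ± 0.34), a NAC factor of the cell cycle checkpoint. DNA replication genes included 16 of 19 that rose and 0 that fell (16 and 1 adjusted over the list alone), median log2 fold change 0.72 (camera adjusted p = 6.5e-04, adjusted p = 0.437 with an estimated correlation). They included RNR1 (1.60 ± 0.15), MCM2 (AT1G44900, 1.01 ± 0.10), of the replicative helicase, and ETG1 (AT2G40550, 1.21 ± 0.14).

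Of 24 cell wall expansion genes, 1 rose and 19 fell (the same adjusted over the list alone), median log2 fold change -1.64 (camera adjusted p = 1.3e-07, adjusted p = 0.178 with an estimated correlation). Among them were the cellulose synthase CESA2 (AT4G39350, -1.76 ± 0.10), XTH19 (-2.98 ± 0.17) and XTH33 (-4.33 ± 0.28). Auxin response genes included 2 of 23 that rose and 18 that fell (the same adjusted over the list alone), median log2 fold change -1.56 (camera adjusted p = 4.4e-04, adjusted p = 0.479 with an estimated correlation). They included IAA19 (AT3G15540, -2.47 ± 0.24) and IAA14 (AT4G14550, -3.33 ± 0.33). Brassinosteroid genes included 1 of 13 that rose and 10 that fell (the same adjusted over the list alone), median log2 fold change -1.05 (camera adjusted p = 9.3e-04, adjusted p = 0.437 with an estimated correlation). Examples were BAS1 (AT2G26710, -3.71 ± 0.27), which inactivates the hormone, and BES1 (-2.22 ± 0.17). The gibberellin list did not pass (median log2 fold change -1.104, camera adjusted p = 0.0965), with members on both sides: RGA (AT2G01570, -1.27 ± 0.10), a DELLA repressor, GA2OX6 (AT1G02400, 2.68 ± 0.23), which inactivates gibberellin, and GA3OX1 (AT1G15550, -4.17 ± 0.35), which makes it. Of 11 root genes, 0 rose and 7 fell (the same adjusted over the list alone), median log2 fold change -2.37 (camera adjusted p = 0.0158, adjusted p = 0.479 with an estimated correlation). Among them were the Casparian strip genes CASP2 (AT3G11550, -4.98 ± 0.47) and CASP1 (AT2G36100, -4.19 ± 0.48). In all, 12771 genes passed, 6541 higher and 6230 lower, and 6417 changed at least 2-fold. In WT libraries rRNA genes took 0.00720 to 0.00789% of counts in the dark, 0.0308 to 0.0382% at the low and 0.362 to 0.468% at the high dose, and organelle genes 0.0197 to 0.0230, 0.0280 to 0.0320 and 0.153 to 0.249%.

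**Figure D2:**
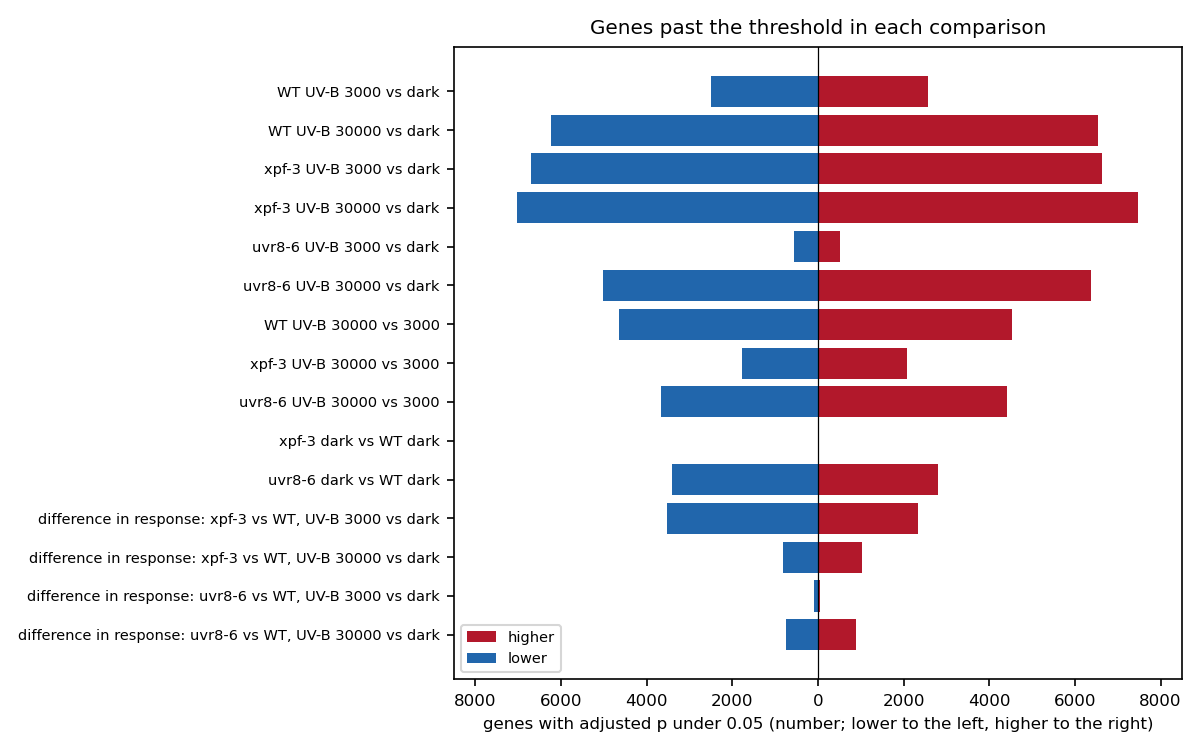
Number of genes with an adjusted p under 0.05 in each of the 15 comparisons (x axis, genes; bars to the right, higher; to the left, lower). WT gave 5064 genes at the low dose and 12771 at the high dose, xpf-3 13329 and 14504, and uvr8-6 1090 and 11415.

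The doses were compared within WT to find what the higher dose added. CRK39 (AT4G04540), a receptor-like kinase gene, VQ29 (AT4G37710) and the cytochrome P450 CYP715A1 (AT5G52400) went from 0 counts at the low dose to at least 101-, 87.8- and 77.6-fold more. EDA4 was at least 24.0-fold lower, the peroxidase PER16 (AT2G18980) 71.4 times lower (counting interval 24.2 to 348), and the lipid transfer protein gene AZI1 (AT4G12470, -5.53 ± 0.56) fell. Among defence genes, 14 of 17 rose and 0 fell (15 and 0 adjusted over the list alone), median log2 fold change 3.01 (camera adjusted p = 2.2e-08, adjusted p = 0.0906 with an estimated correlation). They included CBP60G (5.42 ± 0.27) and WRKY70 (AT3G56400, 4.14 ± 0.30). Cell wall expansion genes included 1 of 24 that rose and 20 that fell (1 and 21 adjusted over the list alone), median log2 fold change -1.27 (camera adjusted p = 2.5e-08, adjusted p = 0.208 with an estimated correlation). Examples were CESA2 (-1.32 ± 0.10) and COB (AT5G60920, -1.29 ± 0.10). DNA damage response genes included 4 of 28 that rose and 0 that fell (the same adjusted over the list alone), median log2 fold change 0.19 (camera adjusted p = 0.0702). That list passed without WT UV-B 30000 replicate 3 (adjusted p = 0.0340). Of all genes, 9193 passed, 4534 higher and 4659 lower, but 4767 and 4491 with DESeq2 size factors.

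In the dark, xpf-3 was compared with WT to find what the mutation changed without UV-B. After UVH1, APY3 (AT1G14240, 1.25 ± 0.21), an apyrase, DIR14 (AT4G11210, 0.94 ± 0.18), a dirigent protein gene, and the jacalin-related lectin JAL33 (AT3G16450, 0.90 ± 0.12) were higher. BGLU11 (AT1G02850, -1.94 ± 0.33), a beta-glucosidase, OMR1 (AT3G10050, -0.99 ± 0.20), threonine deaminase, ENODL2 (AT4G27520, -0.96 ± 0.15) and NUDX13 (AT3G26690, -0.83 ± 0.13) were lower. Of all genes 33 passed, 21 higher and 12 lower, and 3307 had an unadjusted p under 0.05. No DNA damage response gene passed (median log2 fold change -0.040, or -0.014 with genes at 0 set to their bound, camera adjusted p = 0.365). Among cell wall expansion genes, 0 of 24 were higher and 0 lower (7 and 0 adjusted over the list alone), median log2 fold change 0.31 (camera adjusted p = 4.2e-04, adjusted p = 0.892 with an estimated correlation), and the list did not pass without WT dark replicate 1 (adjusted p = 0.147). Of 11 shoot apex and stomata genes, 0 were higher and 0 lower (0 and 3 adjusted over the list alone), median log2 fold change -1.05 (camera adjusted p = 0.00419, adjusted p = 0.892 with an estimated correlation). That list too did not pass without WT dark replicate 1 (adjusted p = 0.468) or without xpf-3 dark replicate 3 (0.0901). WT dark replicate 1 had a mean of 0.45 log2 CPM over these genes against -1.08 and -0.86 in the other WT dark libraries. The number of genes was 1 in a fit on the 6 dark libraries, 453 with DESeq2, 67 with a replicate block, 14 without WT dark replicate 2, 63 without WT dark replicate 3, and 20 and 20 without xpf-3 dark replicates 1 and 3. Each named gene but UVH1, JAL33, ENODL2 and NUDX13 lost its call when 1 of these or WT dark replicate 1 or xpf-3 dark replicate 2 was left out, with adjusted p up to 0.229 (OMR1, without WT dark replicate 1).

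The low dose in the repair mutant xpf-3 was compared with its dark. DTX3 was 4320.1 times higher (counting interval 1478 to 20951), DTX4 3377 times higher (counting interval 606 to 133410) and PUB21 (AT5G37490), a U-box ubiquitin ligase gene, 2353 times higher (counting interval 422 to 92983). CHS went from 0 counts to 32.9 ± 3.64 CPM, at least 295-fold higher. AGP22 (AT5G53250), an arabinogalactan protein gene, fell from 459 ± 20.8 to 3.34 ± 1.51 CPM (-7.13 ± 0.43), followed by XTH33 (-6.56 ± 0.32), BDG2 (AT5G41900, -6.29 ± 0.48), of cuticle formation, and PME61 (-5.95 ± 0.76). Of all genes 13329 passed, 6620 higher and 6709 lower, but 6755 and 6559 with DESeq2 size factors, and 6914 changed at least 2-fold.

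By list, the low dose in xpf-3 gave these changes. Among DNA damage response genes, 22 of 28 rose and 1 fell (the same adjusted over the list alone), median log2 fold change 2.05 (camera adjusted p = 2.0e-08, adjusted p = 0.175 with an estimated correlation). Leading members were XRI1 (2.73 ± 0.15), TRFL10 (3.495 ± 0.19), BRCA1 (2.997 ± 0.18) and NAC044 (5.99 ± 0.36). Among DNA replication genes, 17 of 19 rose and 0 fell (the same adjusted over the list alone), median log2 fold change 0.81 (camera adjusted p = 1.3e-05, adjusted p = 0.369 with an estimated correlation). They included RNR1 (1.90 ± 0.15), MCM2 (1.02 ± 0.10) and E2FC (AT1G47870, 1.104 ± 0.12). Of 17 mitosis genes, 15 rose and 0 fell (the same adjusted over the list alone), median log2 fold change 0.75 (camera adjusted p = 0.00982, adjusted p = 0.630 with an estimated correlation). The first by p were CDKB1;1 (AT3G54180, 0.71 ± 0.15), a cyclin-dependent kinase, HIK (AT1G18370, 1.205 ± 0.27), a cytokinetic kinesin, PLE (AT5G51600, 1.26 ± 0.32), a microtubule bundler, and KN (AT1G08560, 1.14 ± 0.29), a cytokinesis syntaxin. Among oxidative stress genes, 16 of 21 rose and 3 fell (the same adjusted over the list alone), median log2 fold change 4.41 (camera adjusted p = 1.5e-06, adjusted p = 0.369 with an estimated correlation). Examples were AOX1A (4.53 ± 0.22) and NAC013 (4.41 ± 0.23). For the 17 defence genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone), median log2 fold change 2.05, or 2.01 with genes at 0 set to their bound (camera adjusted p = 4.2e-05, adjusted p = 0.217 with an estimated correlation). Among them were CBP60G (6.88 ± 0.39) and PAD3 (7.69 ± 0.55).

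For the 24 cell wall expansion genes, 0 rose and 22 fell (the same adjusted over the list alone), median log2 fold change -1.48 (camera adjusted p = 1.5e-08, adjusted p = 0.175 with an estimated correlation). Leading members were XTH33 (-6.56 ± 0.32), XTH19 (-3.38 ± 0.18) and CESA2 (-1.70 ± 0.10). Among auxin response genes, 3 of 23 rose and 17 fell (the same adjusted over the list alone), median log2 fold change -1.68 (camera adjusted p = 0.00157, adjusted p = 0.552 with an estimated correlation). They included SHY2 (-2.62 ± 0.22) and IAA19 (-2.73 ± 0.24). Shoot apex and stomata genes, a list for another tissue, did not pass (median log2 fold change 1.47, camera adjusted p = 0.103), though 6 of 11 rose, such as STM (AT1G62360, 1.295 ± 0.35), a meristem homeobox gene.

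At the high dose in xpf-3, FOX1 went from 0 counts to 107 ± 17.7 CPM, at least 937-fold higher than in xpf-3 dark. GSTU12 (AT1G69920), a glutathione transferase gene, TAT3 (AT2G24850), a tyrosine aminotransferase gene, and AOX1D (AT1G32350), an alternative oxidase gene, were at least 636-, 477- and 389.9-fold higher. IBH1 (AT2G43060), a repressor of cell elongation, fell from 37.1 ± 14.7 to 0.379 ± 0.206 CPM (-6.46 ± 0.46), ZFP6 (AT1G67030), a zinc finger gene, was 105 times lower (counting interval 18.5 to 4163) and the sodium transporter HKT1 (AT4G10310) 94.4 times lower (counting interval 25.9 to 783). Of all genes 14504 passed, 7478 higher and 7026 lower, and 8710 changed at least 2-fold. In xpf-3, rRNA genes took 0.0166 to 0.0218% of counts in the dark, 0.0496 to 0.0766% at the low and 0.304 to 0.406% at the high dose, and organelle genes 0.0372 to 0.0857, 0.0524 to 0.641 and 0.141 to 0.276%.

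Mitosis genes included 17 of 17 that rose and 0 that fell (the same adjusted over the list alone), median log2 fold change 1.23 (camera adjusted p = 0.00147, adjusted p = 0.459 with an estimated correlation). Examples were HIK (1.76 ± 0.28), CDKB1;1 (0.90 ± 0.15) and CYCB1;3 (AT3G11520, 1.23 ± 0.21), a B-type cyclin. Shoot apex and stomata genes included 9 of 11 that rose and 0 that fell (the same adjusted over the list alone), median log2 fold change 2.46 (camera adjusted p = 0.0249, adjusted p = 0.459 with an estimated correlation). Among them were STM (2.33 ± 0.33) and TMM (AT1G80080, 2.36 ± 0.42), a stomatal receptor. A fit on these 6 libraries alone lost the shoot apex call (adjusted p = 0.0601). For the 28 DNA damage response genes, 23 rose and 1 fell (the same adjusted over the list alone), median log2 fold change 1.66 (camera adjusted p = 3.3e-06, adjusted p = 0.185 with an estimated correlation). Leading members were XRI1 (2.26 ± 0.15) and TRFL10 (2.79 ± 0.20). For the 23 auxin response genes, 2 rose and 20 fell (the same adjusted over the list alone), median log2 fold change -2.80 (camera adjusted p = 2.9e-06, adjusted p = 0.303 with an estimated correlation). Among them was IAA19 (-3.57 ± 0.26).

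In xpf-3 the doses were compared too. Of 28 DNA damage response genes, 0 rose and 8 fell (0 and 10 adjusted over the list alone), median log2 fold change -0.37 (camera adjusted p = 0.00371, adjusted p = 0.495 with an estimated correlation). Examples were BRCA1 (-0.79 ± 0.16), GMI1 (AT5G24280, -1.12 ± 0.23), a chromosome maintenance gene, and TRFL10 (-0.71 ± 0.16). Of 23 auxin response genes, 1 rose and 17 fell (1 and 18 adjusted over the list alone), median log2 fold change -1.17 (camera adjusted p = 1.8e-10, adjusted p = 0.236 with an estimated correlation). Among them were PIN3 (AT1G70940, -0.92 ± 0.15), an auxin efflux carrier, and GH3.5 (AT4G27260, -1.17 ± 0.20). Of 17 defence genes, 10 rose and 0 fell (the same adjusted over the list alone), median log2 fold change 1.33 (camera adjusted p = 3.0e-05, adjusted p = 0.233 with an estimated correlation). They included WRKY70 (1.67 ± 0.24) and PAD3 (1.90 ± 0.31). VQ29 was 141 times higher (counting interval 38.4 to 1170.4), CYP715A1 (5.95 ± 0.73) rose, and the carbonic anhydrase BCA3 (AT1G23730) was at least 15.1-fold lower. Of all genes 3855 passed, 2073 higher and 1782 lower, and 2448 without xpf-3 UV-B 3000 replicate 2. DESeq2 size factors turned the majority, to 1826 and 2043.

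**Figure D3:**
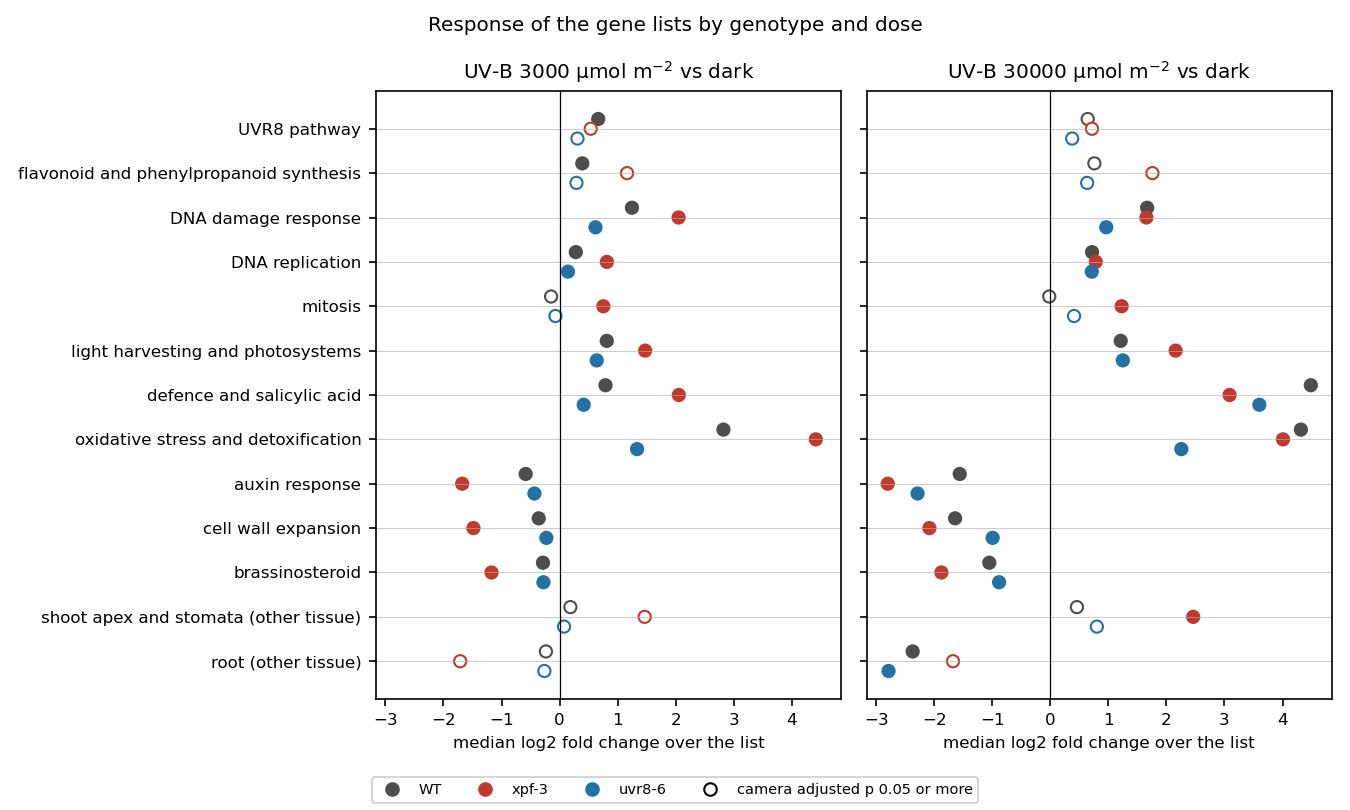
Median log2 fold change against the dark (x axis) of 13 gene lists (y axis) in WT, xpf-3 and uvr8-6 at the low (left) and high dose (right); open circles did not pass the camera test. The mitosis list had medians of 0.75 and 1.23 in xpf-3, -0.15 and -0.018 in WT, and -0.072 and 0.41 in uvr8-6.

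Whether xpf-3 responded differently from WT at the low dose was tested as the difference of the log2 changes, mutant minus WT. Of 24 cell wall expansion genes, 0 were higher and 19 lower (0 and 20 adjusted over the list alone), median difference -1.204 (camera adjusted p = 7.6e-12, adjusted p = 0.126 with an estimated correlation). Among them were CESA2 (-1.27 ± 0.14) and XTH33 (-3.86 ± 0.42). Among brassinosteroid genes, 0 of 13 were higher and 7 lower (0 and 9 adjusted over the list alone), median difference -0.84 (camera adjusted p = 2.3e-04, adjusted p = 0.397 with an estimated correlation). They included BAS1 (-2.07 ± 0.32). Auxin response genes included 1 of 23 that was higher and 10 that were lower (1 and 13 adjusted over the list alone), median difference -0.86 (camera adjusted p = 0.00558, adjusted p = 0.583 with an estimated correlation). An example was PIN3 (-1.19 ± 0.21). Among mitosis genes, 8 of 17 were higher and 0 lower (12 and 0 adjusted over the list alone), median difference 1.02 (camera adjusted p = 2.3e-04, adjusted p = 0.583 with an estimated correlation). Among them was PLE (1.54 ± 0.45). WT dark replicate 1 averaged 3.73 log2 CPM over mitosis genes, against 2.88 and 3.04 in the other WT dark libraries, and without it the median difference was 0.64. The shoot apex list, in which that library also stood apart, did not pass (median difference 1.197, camera adjusted p = 0.0540), but did without WT dark replicates 2 or 3 (adjusted p = 0.0169 and 0.0323). For the 19 DNA replication genes, 10 were higher and 0 lower (12 and 0 adjusted over the list alone), median difference 0.54 (camera adjusted p = 2.2e-05, adjusted p = 0.397 with an estimated correlation). They included MCM6 (AT5G44635, 0.94 ± 0.18). DNA damage response genes included 7 of 28 that were higher and 0 that were lower (the same adjusted over the list alone), median difference 0.41 (camera adjusted p = 8.9e-04, adjusted p = 0.397 with an estimated correlation). Examples were CYCB1;1 (AT4G37490, 1.82 ± 0.29), a cyclin of the damage response, and TRFL10 (1.09 ± 0.27). Defence genes included 6 of 17 that were higher and 0 that were lower (the same adjusted over the list alone), median difference 1.33 (camera adjusted p = 1.6e-05, adjusted p = 0.201 with an estimated correlation). Among them was WRKY70 (2.57 ± 0.44). For the 21 oxidative stress genes, 5 were higher and 1 lower (the same adjusted over the list alone), median difference 0.77 (camera adjusted p = 0.00250, adjusted p = 0.583 with an estimated correlation). They included AOX1A (1.71 ± 0.27). Light harvesting and photosystem genes included 4 of 25 that were higher and 0 that were lower (2 and 0 adjusted over the list alone), median difference 0.57 (camera adjusted p = 0.00260, adjusted p = 0.583 with an estimated correlation).

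The largest single differences at the low dose were fitted for GSTU12 (8.51 ± 2.58), GSTU11 (AT1G69930, 7.46 ± 2.56), WOX1 (AT3G18010), a homeobox gene (7.09 ± 1.98), and DAR3 (AT5G66640, 6.94 ± 0.75), and on the other side ZFP6 (-5.12 ± 0.74), KCS12 (AT2G28630, -4.42 ± 0.56), of long-chain fatty acid synthesis, BDG2 (-4.35 ± 0.61) and TPPB (AT1G78090, -4.12 ± 0.44), trehalose phosphate phosphatase. Fitted differences of genes with 0 counts in a group, such as GSTU12, depend on the prior count. In all 5854 genes differed, 2338 more positive and 3516 more negative in xpf-3. There were 3357 without WT dark replicate 1 and 3885 without WT UV-B 3000 replicate 3. GSTU12, WOX1 and PLE did not pass without WT dark replicate 1 (adjusted p = 0.99997, 0.167 and 0.0865), and GSTU11 without WT dark replicates 2 or 3, WT UV-B 3000 replicate 3 or any xpf-3 dark library (up to 0.181).

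At the high dose the mitosis list was again higher. For the 17 mitosis genes, 10 were higher and 0 lower (13 and 0 adjusted over the list alone), median difference 1.29 (camera adjusted p = 7.3e-09, adjusted p = 0.435 with an estimated correlation). Leading members were CDKB2;1 (AT1G76540, 1.38 ± 0.32) and CYCB1;3 (1.29 ± 0.30). CDKB2;1 went from 20.9 ± 8.06 to 17.3 ± 3.66 CPM in WT, and from 17.3 ± 2.58 to 37.0 ± 6.89 CPM in xpf-3. Among shoot apex and stomata genes, 2 of 11 were higher and 0 lower (6 and 0 adjusted over the list alone), median difference 2.31 (camera adjusted p = 2.0e-04, adjusted p = 0.435 with an estimated correlation). An example was TMM (2.75 ± 0.58). Among light harvesting and photosystem genes, 4 of 25 were higher and 0 lower (the same adjusted over the list alone), median difference 0.66 (camera adjusted p = 3.2e-06, adjusted p = 0.435 with an estimated correlation). Among them were RBCS3B (AT5G38410, 2.15 ± 0.42) and RBCS1B (AT5G38430, 4.87 ± 0.9997), Rubisco relatives with uncertain shared reads. Among auxin response genes, 0 of 23 were higher and 7 lower (0 and 13 adjusted over the list alone), median difference -0.97 (camera adjusted p = 3.2e-06, adjusted p = 0.435 with an estimated correlation). They included IAA2 (AT3G23030, -0.96 ± 0.21). Cell wall expansion genes included 0 of 24 that were higher and 2 that were lower (0 and 6 adjusted over the list alone), median difference -0.46 (camera adjusted p = 2.0e-04, adjusted p = 0.435 with an estimated correlation). An example was EXPA1 (AT1G69530, -1.49 ± 0.29), an expansin.

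The largest single differences at the high dose were fitted for WOX1 (7.29 ± 1.86), SDD1 (AT1G04110, 5.58 ± 1.69), a stomatal protease gene, iqd21 (AT3G49260, 5.49 ± 1.33) and PnsL2 (AT1G14150, 4.996 ± 1.29), and on the other side BCA3 (-7.37 ± 1.61), LECRKA4.2 (AT5G01550, -4.52 ± 1.37), a lectin receptor kinase gene, EXO70H1 (AT3G55150, -3.46 ± 0.90) and PER15 (AT2G18150, -3.44 ± 0.96). WOX1 and BCA3 had groups at 0 counts. In all 1849 genes differed, 1032 more positive and 817 more negative. Single libraries decided this number. It was 177 without WT dark replicate 1, 236 without WT UV-B 30000 replicate 2 and 714 without xpf-3 dark replicate 3. It was 1042 and 1082 without xpf-3 UV-B 30000 replicates 2 and 3. Without WT dark replicate 1, which stood apart in mitosis and shoot apex genes, of the genes named for this comparison BCA3, EXPA1 and RBCS3B passed, and the adjusted p of the others ran from 0.0517 (IAA2) to 0.851 (SDD1). CYCB1;3, TMM, IAA2 and RBCS1B lost their call with that library alone left out, and the rest also without 1 or more others.

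**Figure D4:**
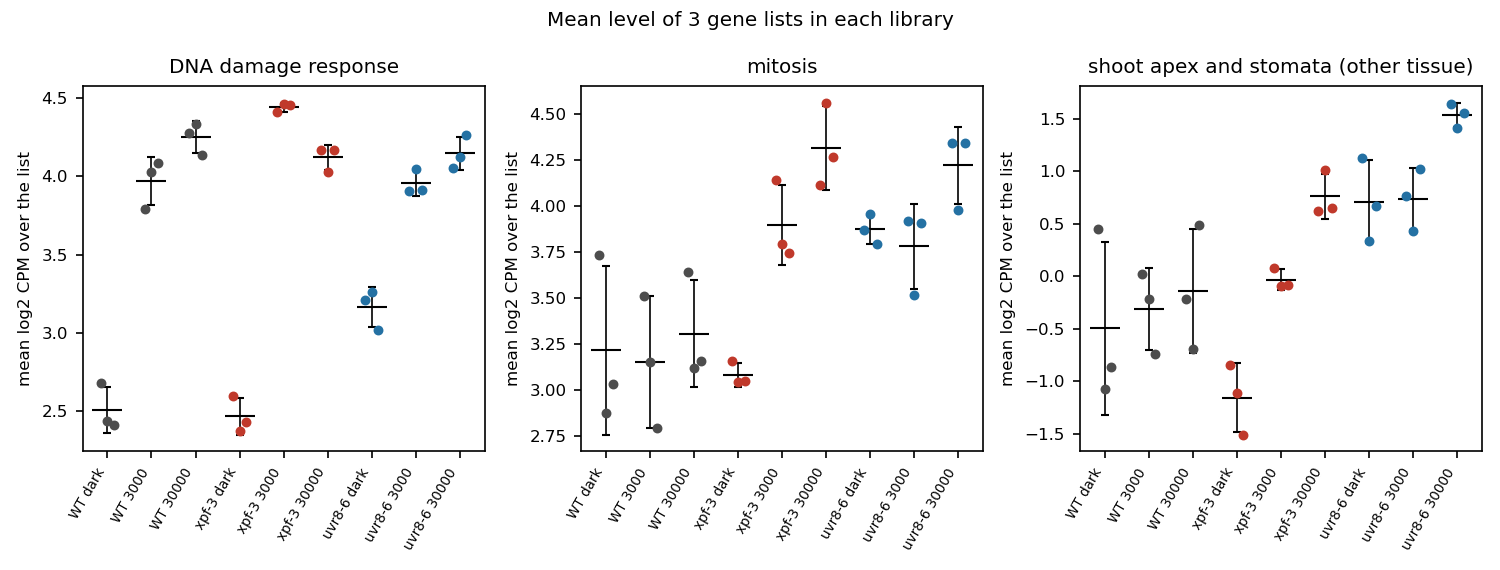
Mean log2 CPM (y axis) over the DNA damage response, mitosis, and shoot apex and stomata lists in each library, by group (points, libraries; bars, mean ± SD of 3). WT dark replicate 1 stood at 3.73 for mitosis.

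**Figure D5:**
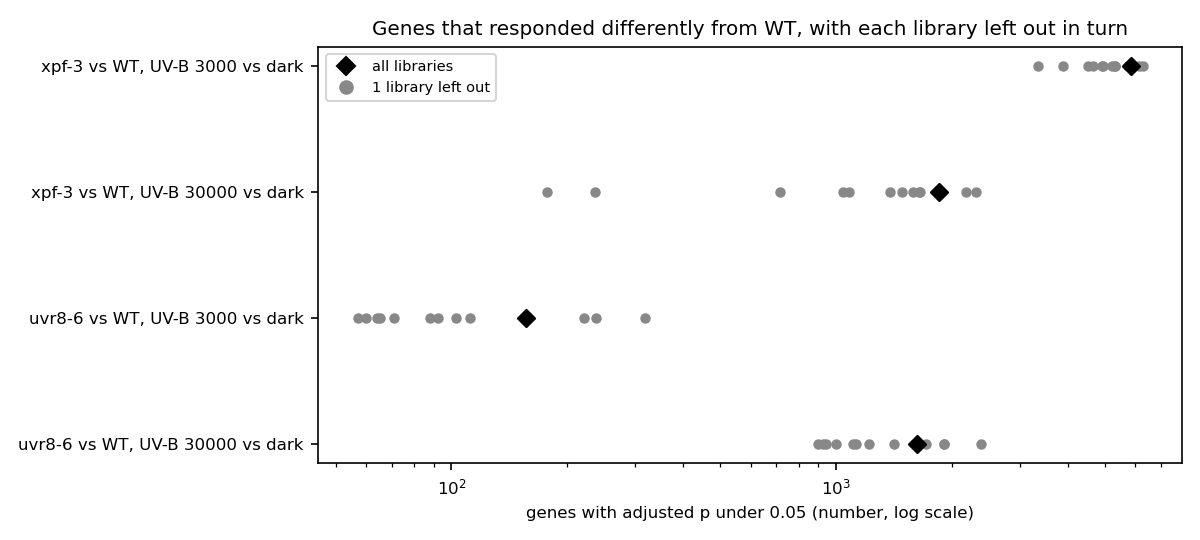
Genes with a different response from WT (x axis, number on a log scale) in the 4 mutant and dose comparisons (y axis), with all libraries (diamonds) and with each library left out (circles). For xpf-3 at the high dose the number ran from 177 to 2316.

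In the dark, uvr8-6 was compared with WT, with run and genotype confounded. CHR34 (AT2G21450), a chromatin remodeller gene, was at least 20.5-fold higher in uvr8-6. The late embryogenesis genes LEA29 (AT3G15670, 6.29 ± 0.85), LEA (AT2G21490, 5.95 ± 0.99), ECP63 (AT2G36640, 5.65 ± 0.79) and GEA6 (AT2G40170, 5.86 ± 1.01) were higher, as were the seed oleosins OLEO2 (AT5G40420, 4.54 ± 0.83) and OLEO1 (AT4G25140, 2.29 ± 0.63), while the seed storage list did not pass (median log2 fold change -0.91, mean -0.084, test direction up, camera adjusted p = 0.579). Root genes did not pass as a list (median log2 fold change 1.43, camera adjusted p = 0.344), with CASP2 (-1.07 ± 0.35) lower and RSL4 (AT1G27740, 2.03 ± 0.66), COBL9 (AT5G49270, 1.73 ± 0.61) and PRP3 (AT3G62680, 1.88 ± 0.68) higher. These 4 lost their calls without replicate 2 of either group (adjusted p up to 0.183), and 1 or more of them without each other library. After UVR8, the largest decreases were in PME61 (-3.20 ± 0.59), ATPMEPCRD (AT2G43050, -3.14 ± 0.74), another pectin methylesterase, and THA1 (AT1G08630, -2.87 ± 0.80), a threonine aldolase gene. Among DNA damage response genes, 12 of 28 were higher and 1 lower (the same adjusted over the list alone), median log2 fold change 0.31 (camera adjusted p = 3.6e-04, adjusted p = 0.735 with an estimated correlation). Leading members were NAC044 (3.06 ± 0.36), GMI1 (1.81 ± 0.25) and PARP2 (1.74 ± 0.25). Of 17 mitosis genes, 7 were higher and 0 lower (the same adjusted over the list alone), median log2 fold change 0.58 (camera adjusted p = 5.9e-04, adjusted p = 0.735 with an estimated correlation). Among them was CDKB1;2 (AT2G38620, 1.14 ± 0.21). For the 11 shoot apex and stomata genes, 1 was higher and 0 lower (the same adjusted over the list alone), median log2 fold change 1.18 (camera adjusted p = 0.00488, adjusted p = 0.735 with an estimated correlation). It was STM (1.94 ± 0.28). Of 21 oxidative stress genes, 9 were higher and 1 lower (the same adjusted over the list alone), median log2 fold change 0.54 (camera adjusted p = 0.00712, adjusted p = 0.735 with an estimated correlation). An example was FER1 (AT5G01600, 0.93 ± 0.14), a ferritin. For the 23 auxin response genes, 1 was higher and 6 lower (2 and 9 adjusted over the list alone), median log2 fold change -0.62 (camera adjusted p = 0.00746, adjusted p = 0.735 with an estimated correlation). Among them was IAA2 (-0.77 ± 0.15). Among cell wall expansion genes, 1 of 24 was higher and 12 lower (the same adjusted over the list alone), median log2 fold change -0.37 (camera adjusted p = 0.0113, adjusted p = 0.735 with an estimated correlation). They included CESA1 (AT4G32410, -0.55 ± 0.11). Of 19794 genes 6223 passed, 2813 higher and 3410 lower. The 6 dark libraries alone gave 2616. Without WT dark replicates 2 or 3, or uvr8-6 dark replicates 1 or 2, the number was 3878, 3668, 4022 and 3732. The auxin call was lost without uvr8-6 dark replicate 2 (adjusted p = 0.0764), the cell wall call without WT dark replicate 2 (0.0666) and THA1 without uvr8-6 dark replicate 1 (0.0553).

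The low dose in uvr8-6, where the photoreceptor transcript was low, was compared with uvr8-6 dark. DTX4 was 761 times higher (counting interval 136 to 30078), PER49 (AT4G36430), a peroxidase gene, 507 times higher (counting interval 90.6 to 20065) and UGT74E1 187 times higher (counting interval 33.1 to 7412), and PXMT1 (AT1G66700, 7.18 ± 0.78), a methyltransferase gene, rose. The cytochrome P450 CYP71B13 (AT5G25140, -2.87 ± 0.64) and UMAMIT17 (-2.68 ± 0.71) fell most. Of DNA damage response genes, 13 of 28 measured members rose, 0 fell and 15 did not pass (22 and 0 adjusted over the list alone). Their median log2 fold change was 0.62 (camera adjusted p = 5.1e-19, adjusted p = 0.00508 with an estimated correlation). XRI1 (1.55 ± 0.14), SMR7 (AT3G27630, 2.86 ± 0.27), a cell cycle inhibitor, BRCA1 (1.70 ± 0.16) and TRFL10 (1.37 ± 0.16) led. Oxidative stress genes included 10 of 21 that rose and 0 that fell (12 and 1 adjusted over the list alone), median log2 fold change 1.33, or 1.197 with genes at 0 set to their bound (camera adjusted p = 5.0e-11, adjusted p = 0.189 with an estimated correlation). Examples were GSTU25 (2.89 ± 0.31) and AOX1A (1.61 ± 0.19). CHS (2.07 ± 0.48) was the only UVR8 pathway gene past the test, and not without uvr8-6 dark replicates 1 or 3 or UV-B 3000 replicate 2 (adjusted p = 0.0545, 0.101 and 0.105). That list did not pass (median log2 fold change 0.31, camera adjusted p = 0.108), though it did without uvr8-6 dark replicate 2 or UV-B 3000 replicates 1 or 3 (9.1e-05, 0.00624 and 0.00599). Without uvr8-6 dark replicate 3, CYP71B13 and UMAMIT17 did not pass (0.125 and 0.181). Nor did UMAMIT17 without any 1 low-dose library (up to 0.104) or dark replicate 1 (0.0683), or CYP71B13 without UV-B 3000 replicate 2 (0.0504).

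Other lists moved in uvr8-6 at the low dose. Of 23 auxin response genes, 0 rose and 3 fell (0 and 5 adjusted over the list alone), median log2 fold change -0.43 (camera adjusted p = 9.4e-04, adjusted p = 0.487 with an estimated correlation). Among them was IAA6 (-1.66 ± 0.35). For the 24 cell wall expansion genes, 0 rose and 3 fell (2 and 10 adjusted over the list alone), median log2 fold change -0.23 (camera adjusted p = 6.6e-04, adjusted p = 0.413 with an estimated correlation). They included XTH33 (-1.49 ± 0.21). In all 1090 genes passed, 520 higher and 570 lower. Replicate 2 of uvr8-6 stood apart at each dose in HY5 (AT5G11260), a bZIP factor of light responses chosen after its values were seen, with 95.5 CPM in its dark library against 23.4 and 21.2 in the others, and 108 against 19.0 and 21.1 after the low dose. The replicate numbers paired these libraries, and a replicate block within each genotype gave 1742 genes. The 6 libraries alone gave 661, and 410 passed without uvr8-6 dark replicate 3, or 513 without UV-B 3000 replicate 2.

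The high dose in uvr8-6 was compared with the dark. CML47 (AT3G47480), a calmodulin-like gene, was at least 649-fold higher, HIPP14 at least 284-fold, AOX1D at least 212-fold and FOX1 1589.5 times higher (counting interval 439.6 to 13131). RTFL13 (AT3G23635), a small peptide gene, and UMAMIT17 were at least 53.8- and 35.5-fold lower. Among defence genes, 16 of 17 rose and 0 fell (the same adjusted over the list alone), median log2 fold change 3.60 (camera adjusted p = 5.6e-08, adjusted p = 0.134 with an estimated correlation). Leading members were CBP60G (7.12 ± 0.33), WRKY70 (5.01 ± 0.29) and PAD3 (8.26 ± 0.48). Among oxidative stress genes, 17 of 21 rose and 1 fell (the same adjusted over the list alone), median log2 fold change 2.26 (camera adjusted p = 1.1e-07, adjusted p = 0.200 with an estimated correlation). The first by p were CYP81D8 (4.82 ± 0.28) and GSTU4 (AT2G29460, 5.37 ± 0.40). For the 28 DNA damage response genes, 22 rose and 0 fell (24 and 0 adjusted over the list alone), median log2 fold change 0.96 (camera adjusted p = 1.3e-06, adjusted p = 0.149 with an estimated correlation). The first by p were XRI1 (1.55 ± 0.14), BRCA1 (1.79 ± 0.16) and SMR7 (2.77 ± 0.28). CHS (3.42 ± 0.44) rose, while the UVR8 pathway list did not pass (median log2 fold change 0.38, camera adjusted p = 0.291) except without uvr8-6 dark replicate 2 (adjusted p = 0.0283). Auxin response genes included 2 of 23 that rose and 19 that fell (the same adjusted over the list alone), median log2 fold change -2.29 (camera adjusted p = 6.7e-09, adjusted p = 0.200 with an estimated correlation). Among them were IAA19 (-2.78 ± 0.25) and IAA6 (-5.52 ± 0.49). Of 24 cell wall expansion genes, 2 rose and 20 fell (2 and 21 adjusted over the list alone), median log2 fold change -0.99 (camera adjusted p = 1.0e-08, adjusted p = 0.149 with an estimated correlation). They included XTH33 (-4.49 ± 0.26) and CESA2 (-1.60 ± 0.10). Of 15 gibberellin genes, 3 rose and 10 fell (4 and 11 adjusted over the list alone), median log2 fold change -0.80 (camera adjusted p = 0.00856, adjusted p = 0.200 with an estimated correlation). An example was GA20OX2 (AT5G51810, -4.14 ± 0.40), of gibberellin synthesis. In all 11415 genes passed, 6382 higher and 5033 lower, or 5720 and 5624 with DESeq2 size factors. In uvr8-6, rRNA genes took 0.0249 to 0.0878% of counts in the dark, 0.0371 to 0.0525% at the low and 0.0933 to 0.282% at the high dose, and organelle genes 0.0684 to 0.286, 0.0849 to 0.0991 and 0.124 to 0.407%.

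Between the doses in uvr8-6, CRK39 and VQ29 were at least 90.8- and 73.5-fold higher at the high dose, and EDA4 was 334 times lower (counting interval 59.6 to 13231). For the 17 defence genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone), median log2 fold change 2.59 (camera adjusted p = 1.6e-09, adjusted p = 0.0686 with an estimated correlation). Among them were CBP60G (5.13 ± 0.27) and WRKY70 (4.81 ± 0.28). Of 19 DNA replication genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone), median log2 fold change 0.54 (camera adjusted p = 3.5e-05, adjusted p = 0.292 with an estimated correlation). They included MCM5 (AT2G07690, 0.71 ± 0.11). DNA damage response genes did not pass as a list (median log2 fold change 0.15, camera adjusted p = 0.185). Of all genes 8072 passed, 4406 higher and 3666 lower, but 3602 and 4195 with DESeq2 size factors.

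Whether uvr8-6 responded differently from WT was tested in the same way, with run and genotype confounded. For the 21 oxidative stress genes, 0 were higher and 9 lower (0 and 11 adjusted over the list alone), median difference -1.45 (camera adjusted p = 9.7e-15, adjusted p = 0.117 with an estimated correlation). Leading members were NAC013 (-2.23 ± 0.29), GSTU25 (-2.22 ± 0.43) and BCS1 (AT3G50930, -2.47 ± 0.49), a mitochondrial ATPase gene. Of 28 DNA damage response genes, 0 were higher and 4 lower (0 and 12 adjusted over the list alone), median difference -0.41 (camera adjusted p = 3.7e-11, adjusted p = 0.0625 with an estimated correlation). The first by p were NAC044 (-3.097 ± 0.44) and PARP2 (-1.69 ± 0.32). CHS (-4.25 ± 0.84) and FLS1 (-3.28 ± 0.70) rose less, while the flavonoid list (median difference -0.31, camera adjusted p = 0.0550) and UVR8 pathway list (median difference -0.34, camera adjusted p = 0.0981) did not pass. With a replicate block within each genotype both passed (adjusted p = 0.0324 and 0.0324). Cell wall expansion genes included 1 of 24 that was higher and 0 that were lower (3 and 0 adjusted over the list alone), median difference 0.12 (camera adjusted p = 0.0150, adjusted p = 0.970 with an estimated correlation). Among them was XTH19 (1.08 ± 0.23). That call was lost without any of several libraries, such as replicate 2 of WT or uvr8-6 dark (adjusted p = 0.224 and 0.123). The largest positive differences were fitted for DIR23 (2.97 ± 0.51), PER9 (AT1G44970, 2.87 ± 0.65) and DIR16 (AT3G24020, 2.75 ± 0.58). They fell in WT (-2.82, -3.35 and -2.86) and did not pass in uvr8-6. Most negative were SMP1 (AT3G12960, -6.55 ± 1.50), CHR34 (-5.76 ± 1.07) and LECRKA4.2 (-5.45 ± 1.02). SMP1 and CHR34 had 0 counts in WT dark and LECRKA4.2 had 1, so their values depend on the prior count or 1 read. In all 156 genes differed, 51 more positive and 105 more negative. DESeq2 gave 263 and the 12 libraries alone 53. There were 318 without WT dark replicate 1, 237 without WT UV-B 3000 replicate 1 and 57 to 103 without any 1 of 8 others. NAC013, NAC044, PARP2 and DIR23 passed without each library in turn. The other named genes each lost their call without 1 or more of the 12 libraries except WT UV-B 3000 replicate 1, such as CHS without uvr8-6 dark replicate 2 (adjusted p = 0.155) and WT dark replicates 2 and 3 (0.0630 and 0.0673).

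The difference of responses was also taken at the high dose. Of 21 oxidative stress genes, 0 were higher and 12 lower (0 and 14 adjusted over the list alone), median difference -1.35 (camera adjusted p = 6.3e-11, adjusted p = 0.180 with an estimated correlation). They included NAC013 (-2.34 ± 0.29) and AOX1A (-1.35 ± 0.27). DNA damage response genes included 0 of 28 that were higher and 10 that were lower (0 and 12 adjusted over the list alone), median difference -0.60 (camera adjusted p = 2.4e-07, adjusted p = 0.180 with an estimated correlation). Examples were NAC044 (-3.09 ± 0.44), NAC085 (AT5G14490, -4.86 ± 0.78) and PARP2 (-1.54 ± 0.33). MYB111 (AT5G49330, 2.80 ± 0.61), a flavonol regulator gene, fell in WT (-2.17 ± 0.51) and did not pass in uvr8-6 (0.63 ± 0.33). CHS (-3.25 ± 0.84) rose less, but not past the test without WT dark replicates 2 or 3 or uvr8-6 dark replicate 2 (adjusted p = 0.0588, 0.0691 and 0.112). Of 13 jasmonate genes, 1 was higher and 4 lower (1 and 6 adjusted over the list alone), median difference -0.94 (camera adjusted p = 0.00384, adjusted p = 0.180 with an estimated correlation). By p, JAZ9 (AT1G70700, 1.41 ± 0.26), a repressor gene that fell less in uvr8-6 than in WT, came first, followed by LOX4 (AT1G72520, -1.53 ± 0.35), a lipoxygenase. Among auxin response genes, 0 of 23 were higher and 2 lower (0 and 5 adjusted over the list alone), median difference -0.69 (camera adjusted p = 0.00144, adjusted p = 0.925 with an estimated correlation). They included IAA5 (AT1G15580, -1.88 ± 0.29). Among cell wall expansion genes, 6 of 24 were higher and 0 lower (7 and 0 adjusted over the list alone), median difference 0.21 (camera adjusted p = 0.0150, adjusted p = 0.925 with an estimated correlation). Examples were XTH19 (1.31 ± 0.23) and COB (0.79 ± 0.14). That call was lost without replicate 2 of WT or uvr8-6 dark (adjusted p = 0.0986 and 0.0763). The largest single differences were fitted for AZI1 (3.89 ± 0.87), RLM3 (AT4G16990, 3.48 ± 0.87), SBT5.6 (AT5G45650, 2.81 ± 0.70), a subtilase gene, and DIN10 (AT5G20250, 2.79 ± 0.34), higher, and TAT3 (-6.90 ± 1.099), SMP1 (-6.63 ± 1.304), FAMT (AT3G44860, -5.96 ± 1.07) and CHR34 (-5.80 ± 1.095), lower. In WT dark SMP1 and CHR34 had 0 counts, TAT3 2, FAMT 1 and NAC085 0.028 CPM, so these values are uncertain. In all 1625 genes differed, 887 more positive and 738 more negative, and DESeq2 size factors turned that majority, to 645 and 866. Without replicate 2 of WT dark, WT UV-B 30000 or uvr8-6 dark, or uvr8-6 UV-B 30000 replicate 1, there were 896 to 997. RLM3 did not pass without WT UV-B 30000 replicate 2 (adjusted p = 0.0562).

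To compare 2 genotypes, lists were taken from the third (adjusted p under the threshold and at least 2-fold). For uvr8-6 against WT the third, xpf-3, shares the WT run, so its genes may favour WT. Of 3791 genes that rose in xpf-3 at the low dose, the median log2 fold change was 0.62 in WT and 0.33 in uvr8-6, with a median difference of -0.28 (camera adjusted p = 1.6e-26, and adjusted p = 0.00651 with an estimated correlation). The 3123 genes that fell there had -0.66 in WT and -0.38 in uvr8-6. At the high dose, the 4942 genes that rose had 1.24 in WT and 0.96 in uvr8-6, and the 3768 that fell -1.50 and -1.097. On genes called in uvr8-6, xpf-3 changed more than WT at the low dose: medians of 4.45 against 3.20 over 319 higher genes, and -3.23 against -1.65 over 210 lower genes (camera adjusted p = 1.2e-16 and 6.5e-20; adjusted p = 0.0639 and 0.0639 with an estimated correlation). At the high dose the median difference was 0.13 over the higher genes and -0.26 over the lower ones (camera adjusted p = 0.0312 and 7.6e-04, and adjusted p = 0.464 and 0.464 with an estimated correlation). The first lost its call or turned its sign with 17 of the 27 libraries left out. The other was -0.17 without xpf-3 dark replicate 3 and did not pass.

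Across 19794 genes, the response of xpf-3 to the low dose was set beside that of WT to the high dose, which share no library. Pearson's r was 0.864 and Spearman's rho 0.858. Genes are not independent replicates, so no p is given. It was 1 of 12 pairs of genotypes and doses compared. WT and xpf-3 had r = 0.902 at the high dose and 0.787 at the low dose, WT and uvr8-6 0.893 and 0.749, and xpf-3 and uvr8-6 0.880 and 0.706.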

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

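The tests of the level of DNA damage response genes in uvr8-6 dark and of the uvr8-6 run were chosen only after the results were seen. Each result here, the uvr8-6 dark comparison aside, is a tested log2 difference, mutant minus WT, in the response to UV-B. Values of GSTU12, GSTU11, WOX1, BCA3, SMP1 and CHR34, each with a group at 0 counts, depend on the prior count. TAT3, FAMT and LECRKA4.2 had 1 or 2 counts in WT dark. With an estimated correlation no fixed list passed in these comparisons.

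The mitosis list responded more in xpf-3 than in WT at the high dose, with a median difference of 1.29 (camera adjusted p = 7.3e-09, adjusted p = 0.435 with an estimated correlation). With the mean level of the 11 shoot apex and stomata genes as a term, it fell to 0.53 (camera adjusted p = 0.00193) and 7 genes differed in all instead of 1849; of the 10 members that passed by edgeR, 0 did (3 at an unadjusted p; 0 by DESeq2). The apex list itself differed by 2.31, so a larger share of apex tissue in these libraries may account for part of the pattern, though a term so close to the comparison also removes what the genotype brings. Without WT dark replicate 1 the median was 0.90 (adjusted p = 2.3e-07) and 0 members passed by edgeR (11 at an unadjusted p; 3 by DESeq2), between the values that would have told for or against that library, so its part cannot be told apart. An effect of the xpf-3 genotype on division after UV-B stays open.

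In uvr8-6 the DNA damage response list rose less than in WT at the low dose, by a median of -0.41 (adjusted p = 0.0625 with an estimated correlation). The slope of uvr8-6 on WT changes over the list was 0.449. It lay inside the central 95% of 10000 random sets of genes called in xpf-3 (0.252 to 0.804). That range is wide, so the test leaves open a response weaker over all genes, such as a lower effective dose, and does not tell for it. At the high dose the median rise over the list in uvr8-6 was still under that of WT at the low dose. The list was also higher in uvr8-6 than in WT in the dark (median 0.31, 12 members higher and 1 lower; adjusted p = 0.735 with an estimated correlation) and level with it at the low dose (-0.034, 1 higher and 3 lower), so the smaller rise may start from a higher dark level. Run and uvr8-6 genotype hold the same libraries and cannot be told apart.

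In the dark 6223 genes differed between uvr8-6 and WT. Removing trends over GC content and exon length left 5887, and thinning to the lowest total 4540, which argues against either as the whole cause. Between xpf-3 and WT dark, which share a run, 33 differed, but no WT library lies in the uvr8-6 run, so run and genotype cannot be told apart.

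Genes of a different response numbered 5854 in xpf-3 at the low dose. Of 100 divisions of the 12 libraries, with genotype labels exchanged within each dose, 5 gave as many as the real one (4701 in a fit on these libraries; highest other 5083). In the 4 response comparisons, divisions that exchanged dosed libraries gave at most 12, 12, 13 and 509 genes. In each only 9, the real one among them, kept those libraries in place, too few for a share under 0.05. Medians were 0.41 for DNA damage response, 0.54 DNA replication, 1.02 mitosis, -0.86 auxin response, -1.204 cell wall expansion, -0.84 brassinosteroid, 0.57 light harvesting, 1.33 defence and 0.77 oxidative stress genes. Single genes were XTH33 -3.86, ZFP6 -5.12, GSTU12 8.51, GSTU11 7.46, PIN3 -1.19, TPPB -4.12, BAS1 -2.07, KCS12 -4.42, WOX1 7.09, AOX1A 1.71, WRKY70 2.57, CYCB1;1 1.82, CESA2 -1.27, TRFL10 1.09, BDG2 -4.35, MCM6 0.94, PLE 1.54, DAR3 6.94.

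There were 1849 at the high dose in xpf-3, and 6 of 100 divisions gave as many (732; highest other 2498). Other medians were -0.97 for auxin response, -0.46 cell wall expansion, -0.47 brassinosteroid, 0.66 light harvesting and -0.42 ethylene genes. Single genes were SDD1 5.58, PnsL2 4.996, BCA3 -7.37, EXPA1 -1.49, CDKB2;1 1.38, TMM 2.75, PER15 -3.44, CYCB1;3 1.29, WOX1 7.29, IAA2 -0.96, iqd21 5.49, EXO70H1 -3.46, LECRKA4.2 -4.52, RBCS3B 2.15, RBCS1B 4.87.

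For uvr8-6 at the low dose there were 156, and 2 of 100 divisions gave as many (53; highest other 5069). Medians were 0.12 for cell wall expansion and -1.45 for oxidative stress genes. Single genes were GSTU25 -2.22, NAC013 -2.23, PER9 2.87, DIR23 2.97, CHR34 -5.76, NAC044 -3.097, SMP1 -6.55, DIR16 2.75, BCS1 -2.47, PARP2 -1.69, XTH19 1.08, LECRKA4.2 -5.45, FLS1 -3.28, CHS -4.25.

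At the high dose in uvr8-6 there were 1625, and 4 of 100 divisions gave as many (602; highest other 5778). In both uvr8-6 comparisons the highest numbers, far above the real ones, came with libraries exchanged in the dark, where uvr8-6 and WT differ, so they may reflect that difference. Medians were -0.60 for DNA damage response, -0.69 auxin response, 0.21 cell wall expansion, -1.35 oxidative stress and -0.94 jasmonate genes. Single genes were IAA5 -1.88, NAC013 -2.34, JAZ9 1.41, MYB111 2.80, LOX4 -1.53, CHR34 -5.80, TAT3 -6.90, NAC044 -3.09, SMP1 -6.63, AOX1A -1.35, FAMT -5.96, PARP2 -1.54, AZI1 3.89, RLM3 3.48, XTH19 1.31, CHS -3.25, NAC085 -4.86, DIN10 2.79, SBT5.6 2.81, COB 0.79.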

How the results depend on the processing

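The authors' size factors, the replicate block within each genotype, the fit without the libraries that stand apart, the GC and length correction and thinning were tests chosen only after the results were seen.

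Most values kept their direction and their side of the threshold. Of the values for single genes under an alternative, 4030 did, 203 no longer passed and 0 turned. For the lists of genes, 4522 did, 185 no longer passed, 145 passed newly and 0 turned. A replicate block over all libraries, checked for the comparisons whose libraries the numbers do not pair, moved the xpf-3 dark number to 67. With it, PRP3 and COBL9 in uvr8-6 dark (adjusted p = 0.0523 for each) and dark growth and heat shock genes between the doses in xpf-3 no longer passed (adjusted p = 0.0537 and 0.0526) and flavonoid genes of the uvr8-6 response at the low dose did (0.0459), and it changed no other call. The cause was not tested for the changes below unless one is given.

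DESeq2 called 453 genes between xpf-3 and WT in the dark, and 263 for the uvr8-6 response at the low dose. Fits on the compared groups alone gave 4914 genes between the doses in xpf-3, more than with all libraries, and lower numbers in the other comparisons, down to 1 for xpf-3 dark, 2616 uvr8-6 dark, 3023 WT and 661 uvr8-6 at the low dose, 732 for the xpf-3 response at the high dose, and 53 and 602 for the uvr8-6 response. UVH1 in xpf-3 dark then stood at 1.19 without passing. With a replicate block within each genotype, 1742 genes changed in uvr8-6 at the low dose, and 6 lists instead of 3 differed in its response. Without the libraries that stand apart, 56 genes differed in xpf-3 dark, 3293 and 205 in the xpf-3 responses, and 7 lists in the uvr8-6 response at the low dose. With a correlation estimated from the libraries, camera passed 1 list, DNA damage response, in WT and in uvr8-6 at the low dose and 0 in the other 13 comparisons, where the preset correlation passed 3 to 11.

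The median difference between xpf-3 and WT at the high dose over genes higher in uvr8-6 was 0.046 with DESeq2 size factors and did not pass, and turned to -0.011 with no low-count filter, -0.041 without WT dark replicate 1, -0.020 and -0.021 without xpf-3 UV-B 30000 replicates 1 and 3, and -0.034 without uvr8-6 UV-B 30000 replicate 1. With an estimated correlation the medians over genes called in uvr8-6 (0.13, -0.26, 0.99 and -1.52) did not pass. With no filter the correlation of xpf-3 at the low with WT at the high dose was 0.723 (Spearman 0.711).

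With each library left out in turn, genes ran from 14 to 63 for xpf-3 dark, 3668 to 7827 uvr8-6 dark, 410 to 1347 uvr8-6 at the low dose, 2448 to 3077 between the doses in xpf-3, 3357 to 6272 and 177 to 2316 for the xpf-3 responses, and 57 to 318 and 896 to 2377 for those of uvr8-6. Lists ran from 1 to 7 for xpf-3 dark (without WT dark replicates 1 and 2), 7 to 10 between the doses in xpf-3 (without UV-B 3000 replicates 3 and 1) and 2 to 8 for the uvr8-6 response at the low dose (without WT dark replicates 2 and 1). The medians over genes called in uvr8-6 at the high dose ran from -0.041 to 0.26 (higher) and -0.39 to -0.17 (lower), and Pearson's r of xpf-3 with WT from 0.817 to 0.873.

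DESeq2 size factors moved the median of all genes by at most 0.1 in each comparison. The lowest total, 4508097 counts, limits what was seen of rare transcripts: thinned to it, the uvr8-6 dark comparison called 4540 genes.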

Other observations

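Other hormone and stress genes changed at the high dose in WT, to which the values here belong unless another genotype is named, without their lists passing. Ethylene genes had a median of 0.38 (camera adjusted p = 0.179; 7 of 15 rose and 2 fell), yet ERF2 (AT5G47220) rose in WT, xpf-3 and uvr8-6 (6.21 ± 0.51, 5.95 ± 0.52 and 4.30 ± 0.43). Heat shock genes had a median of 1.76 (camera adjusted p = 0.1004; 9 of 16 rose and 2 fell), while the small heat shock protein gene HSP23.6 (AT4G25200, 6.04 ± 0.85) rose. Abscisic acid genes had a median of -0.66 (camera adjusted p = 0.669; 3 of 12 rose and 6 fell), with LTI30 (AT3G50970) higher (2.94 ± 0.36) and RD29A (AT5G52310, -3.39 ± 0.41) lower. UV lesion repair genes had a median of 0.29 (camera adjusted p = 0.481; 8 of 22 rose and 3 fell): DDB1B (AT4G21100, 0.68 ± 0.11) and XPB2 (AT5G41360, 0.75 ± 0.14) rose, and RAD23C (AT3G02540, -0.82 ± 0.13) and UVH3 (AT3G28030, -0.71 ± 0.17) fell. Seed storage genes had a median of -0.025 (camera adjusted p = 0.888; 0 of 7 rose and 0 fell).

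Of dark growth and shade genes at the high dose, 0 of 14 rose and 10 fell (the same adjusted over the list alone) in WT (median log2 fold change -1.24, camera adjusted p = 0.0158, adjusted p = 0.433 with an estimated correlation), such as PIF1 (AT2G20180, -1.47 ± 0.15) and PIF4 (AT2G43010, -1.84 ± 0.25). The list was lower also in xpf-3 (2 of 14 rose and 10 fell (the same adjusted over the list alone); median log2 fold change -1.299, camera adjusted p = 0.0201, adjusted p = 0.303 with an estimated correlation) and in uvr8-6 (2 of 14 rose and 8 fell (2 and 10 adjusted over the list alone); median log2 fold change -0.66, camera adjusted p = 0.0103, adjusted p = 0.217 with an estimated correlation). Of 21 lists, 11 and 10 moved in WT at the low and high dose, 9 and 11 in xpf-3, and 10 and 11 in uvr8-6 (preset correlation).

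The 10 divisions of 6 libraries into 3 and 3 are too few for a share under 0.05. For each dose comparison and for uvr8-6 dark 1 of the 10, the real one, gave as many genes: real numbers 3023 and 10826 in WT, 12503 and 13348 in xpf-3 and 661 and 10054 in uvr8-6 at the low and high dose, 8113, 4914 and 7085 between the doses, and 2616 for uvr8-6 dark. The highest other division gave 0 by edgeR in each. For xpf-3 dark 2 gave as many, with 1 gene in the real and 2 in the highest other.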
